A study of Mus musculus with 6 samples.

How the data were processed

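RNA from virgin mouse mammary gland was measured on 6 Agilent 2-colour whole mouse genome arrays, 1 array for each combination of 3 cell populations and 2 genotypes. The populations were P4 (CD24+CD29hi, enriched for mammary stem cells), P5 (CD24+CD29lo, enriched for luminal progenitors) and total mammary epithelial cells (MEC), from wild-type mice and from mice heterozygous for ΔNp63, the p63 isoform class that lacks the N-terminal transactivation domain. The labels do not say how many mice contributed to an array. On every array the sample carried Cy5 and the Universal Mouse Reference RNA, a mix of 11 mouse cell lines, carried Cy3. No array had the dyes swapped. The 4 sorted samples lay on slide 1 and both MEC samples on slide 2. On slide 1 WT P4 and WT P5 were at positions 1 and 2, and het P4 and het P5 at 3 and 4. On slide 2 WT MEC was at position 1 and het MEC at 2.

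Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 9.5.3.1. The deposited scanner files give the mean signal of each spot and the median of its local background as raw intensity without normalization. They also hold a deposited log10 ratio of Cy5 over Cy3 after the software's own background subtraction and dye normalization. The deposited series table holds log2 ratios. Set against the scanner files probe by probe, its columns followed the scanner software's log ratios with correlations across probes of 0.988 to 1.000, so its direction is sample over reference. No genome build is stated for the probes and no position is given here.

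Each array had 45018 spots, of which 1639 were controls. Between 32233 and 38946 spots per array were well above background in Cy5, and the median Cy5 signal was 3.28 to 5.22 times the median local background. At most 1 spot per array was saturated in Cy5. Spots marked by the scanner software as non-uniform or as outliers, 74 to 236 per array, were left out. The number of arrays limits the precision of every value.

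Values were computed in R 4.3.3 with limma 3.58.1, data.table (version 1.17.8), jsonlite 2.0.0 and matrixStats 1.5.0. Mean signals and median local backgrounds entered normexp background correction with an offset of 50, followed by loess within each array, and spots of the same probe were averaged. Quantile normalization of the average intensities between arrays leaves the log ratios as they are after loess, so it was used only for Cy5 levels. Probes were named by RefSeq accession (22951 of 41174 probes), by an unambiguous synonym (3109) or by the symbol on the array. Probes well above background in Cy5 on at least 2 of the 6 arrays were kept, and each gene was represented by its probe with the highest mean Cy5 level, which left 24827 of 27670 genes. Values are log2(sample over reference), and differences are given as the first group minus the second.

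With 1 array per group, no group has replicates. The additive limma fit held population and genotype and left 2 residual degrees of freedom. Its genotype coefficient is the mean of the het minus WT differences of the 3 populations, which need not go the same way. The residual of the fit holds population-by-genotype differences as well as noise. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Slide is absorbed by the population term, so the genotype and P4 against P5 tests are unchanged by it and no separate block was fitted. This does not cover position on the slide. In every population the het array lay at a later position than the WT array, so genotype and position cannot be told apart. P4 or P5 against MEC compares different slides, and slide and population cannot be told apart there. Within 1 population the genotypes were compared as differences of 1 array against 1, without a test, and genes at least 2-fold apart were counted. The pooled spread of 245 probes printed 10 times on each array gave the technical error.

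The 22 gene lists were fixed before the data were examined, as were the tests, thresholds and most alternatives. They cover Wnt receptors, Wnt feedback and target genes, Wnt ligands, the Notch pathway, p63-linked epithelial genes, hemidesmosome and basement membrane, basal keratins and myoepithelial contractile genes, general luminal, hormone-sensing luminal and luminal progenitor genes, milk and alveolar genes, mesenchymal transcription factors, cell cycle, immediate-early and heat shock genes, interferon response, and markers of fibroblasts, endothelium, immune cells, adipocytes, erythroid cells, muscle and Schwann cells. Of their members, Wnt4, Jag2, Hey1 and Sox10 each sit on more than 1 list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Within a population a list's median was set against 10000 random lists of equal size matched on mean level in 20 bins. A list was called outside when its median left the central 95% of those lists.

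Named genes followed a rule written beforehand. Trp63 and Fzd7 are given in every comparison. For each list, up to 4 members with the largest absolute difference are eligible if they were well above background. For each tested comparison the rule takes the 5 highest and 5 lowest differences among called genes that moved the same way in both matched pairs. For each population it takes the 5 highest and 5 lowest genotype differences among genes above background and unsaturated on both arrays. It adds the 5 most extreme genes at least 2-fold apart in the same direction in all 3 populations. Of the genes eligible through lists, those that bear on a comparison are given. The result of 1 eligible gene is not reported here. The probes for Trp63 do not separate its ΔN and TA isoforms and may lie outside the deleted part.

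The alternatives set in advance were an offset of 0, the scanner software's log ratio, the series table, the Cy5 channel alone, median centring, no filter or a strict filter on dim probes, the mean over probes, leaving out each array, P4 and P5 arrays alone, the other factor left out of the fit, a trended and robust variance prior, a log2 size of 1.5, estimated correlation and fry. A further alternative was chosen after values had been seen, those of Trp63 included. A few local backgrounds were far above the rest: up to 14 per array and channel exceeded an intensity of 100, the highest at 30168 on the WT P4 array in Cy3. They moved the background mean estimated by normexp to as low as -558.69, against -6.95 to -0.83 once the backgrounds that the scanner software marks as outliers (237 to 935 per array and channel) were replaced by the median of the unmarked ones. In all, 9 sets of normalized values were looked at. The results given first use the backgrounds as deposited, as planned, and for the log2 differences of genes and lists the value with outlier backgrounds replaced is given as well where it differs in direction, in a call or by over 1.5 times. That alternative was also combined with an offset of 0, with median centring and with an estimated correlation.

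The fit was tested on simulated data made from the real arrays, with 200 probes of 36425 shifted at each of 3 sizes. For genotype, 127, 194 and 199 of 200 were recovered at log2 shifts of 1, 2 and 4, with 31 false calls. For P4 against P5, 66, 182 and 194 of 200 were recovered, with 21 false calls. A list of 20 probes shifted by 1 reached a camera p of 1.75e-32 and an unshifted list 0.523. The simulated genotype shift was equal in all 3 populations. Noise was drawn independently for each probe, so the simulation cannot check the preset inter-gene correlation. Figures were drawn with matplotlib 3.10.9.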

Results

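The data are expression profiles of 3 mammary cell populations from virgin C57/B6 mice of 2 genotypes, wild type (WT) and heterozygous for ΔNp63 (het), with 1 array for each of the 6 groups. No group had a replicate, so a spread between animals of a group is not available. P4 and P5 are populations sorted on the surface proteins CD24 and CD29 and enriched for mammary stem cells and for luminal progenitors, and MEC stands for total mammary epithelial cells. Between 74.3% (WT P4) and 89.8% (het MEC) of the spots were well above background in the sample channel. Across genes, which are not independent replicates, the WT and het arrays of 1 population correlated with r = 0.892 in P4, 0.924 in P5 and 0.902 in MEC, and the WT P4 and WT P5 arrays with r = 0.631. The series title places the study around ΔNp63 and stem cell activity in the gland, which makes the genotype comparison within each population its central question and the contrast of P4 with P5 its reference.

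P4 was first compared with P5, with 2 arrays per population, 1 of each genotype. In the additive limma fit 2624 of 24827 genes passed an adjusted p of 0.05, 1251 higher and 1373 lower in P4. Replacing outlier backgrounds gave 3716 genes, 1873 higher and 1843 lower, and 2534 genes were called in the same direction both ways. The P4 and P5 arrays alone, which share a slide, gave 4639 genes, 2285 higher and 2354 lower. Leaving out any 1 of the WT P4, WT P5, het P4 or het P5 arrays left 0 called genes, with 3776 to 5869 at an unadjusted p under 0.05.

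The genes highest in P4 were smooth muscle genes of the myoepithelial lineage. Cnn1 was higher by 6.90 (SE 0.29, adjusted p = 0.00611), Myl9 by 6.28 (SE 0.35, adjusted p = 0.00692), Tpm2 by 6.26 (SE 0.28, adjusted p = 0.00622) and Tagln by 6.21 (SE 0.25, adjusted p = 0.00611). Id4, a transcriptional regulator, was higher by 5.80 (SE 0.46, adjusted p = 0.0104). The genes lowest in P4 were Tspan1 at -5.84 (SE 0.62, adjusted p = 0.0152), Dmbt1 at -5.68 (SE 0.85, adjusted p = 0.0288), Aldh1a3 at -5.57 (SE 0.31, adjusted p = 0.00678), Clca1 at -5.57 (SE 0.25, adjusted p = 0.00622) and Tlcd4 at -5.46 (SE 0.68, adjusted p = 0.0206). Among luminal progenitor genes Elf5 stood at -4.76 (adjusted p = 0.00611) and Kit at -3.66 (adjusted p = 0.00909).

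Trp63 itself was higher in P4 than in P5 by 4.18 (SE 0.26, adjusted p = 0.00745). Fzd7, a Wnt receptor, was higher by 2.35 (SE 0.24, adjusted p = 0.0144). The range for Trp63 over the alternatives was 1.45 to 5.17, the lowest with the mean over its 3 probes, and for Fzd7 1.31 to 2.83. Neither stayed past the threshold when 1 of the 4 sorted arrays was left out. Without WT P4 the adjusted p was 0.0979 for Trp63 and 0.148 for Fzd7, without WT P5 0.106 and 0.134, without het P4 0.129 and 0.183, and without het P5 0.0635 and 0.0694.

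Of the 22 gene lists, 11 passed camera in P4 against P5. The basal keratins and myoepithelial contractile genes had a mean difference of 3.89 (adjusted p = 1.18e-20), and 20 of 20 members were called higher, 20 adjusted over the list alone. The general luminal list had a mean of -2.92 (adjusted p = 6.92e-14), with 14 of 17 members called lower and 15 adjusted over the list alone. The hormone-sensing luminal list had a mean of -2.51 (adjusted p = 4.32e-10), with 10 of 17 members called lower and 10 adjusted over the list alone. The luminal progenitor list had a mean of -1.81 (adjusted p = 1.12e-06), with 7 of 15 members called lower and 9 adjusted over the list alone. Hemidesmosome and basement membrane genes had a mean of 1.62 (adjusted p = 2.26e-07), with 12 of 17 members called higher and 13 adjusted over the list alone, Col17a1 at 5.09 among them. None of the 11 calls held with an estimated correlation. The first 5 lists named here each gave adjusted p = 0.405 with an estimated correlation. By fry, which asks whether a list moves on balance and not against other genes, these 5 had adjusted p between 0.0202 and 0.0285. Of the other 6 called lists, Wnt feedback and target genes passed by fry (adjusted p = 0.0285), and 5 did not, with adjusted p between 0.0948 and 0.197.

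Wnt genes also differed between P4 and P5. The Wnt feedback and target list had a mean of 1.02 (adjusted p = 5.19e-06, and adjusted p = 0.429 with an estimated correlation). Of its 23 members 9 were called higher and 1 lower, and 18 were called adjusted over the list alone. Nkd1 was higher in P4 by 5.13 (adjusted p = 0.0109) and Dkk3 by 3.19 (adjusted p = 0.00622). The Wnt receptor list had a mean of 0.59 (adjusted p = 0.0314, and adjusted p = 0.616 with an estimated correlation), with 4 of 18 members called higher and 7 adjusted over the list alone, among them Lgr5 at 2.62 (adjusted p = 0.0265) and Lgr4 at 2.38 (adjusted p = 0.0343). Its mean was 0.93 with outlier backgrounds replaced (adjusted p = 0.00151). Wnt ligands went both ways, with a mean of 0.07 (adjusted p = 0.815), or 0.20 with outlier backgrounds replaced (adjusted p = 0.566), Wnt10a at 4.66 (adjusted p = 0.012) and Wnt4 at -3.17 (adjusted p = 0.0326). Notch pathway genes had a mean of 0.30 (adjusted p = 0.764), or 0.46 with outlier backgrounds replaced (adjusted p = 0.44), with Jag2 at 4.11 (adjusted p = 0.0116), Dll1 at 3.95 (adjusted p = 0.00611) and Notch3 at -2.07 (adjusted p = 0.00904).

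Another 4 lists passed the threshold. Mesenchymal transcription factors had a mean of 1.10 (adjusted p = 7.93e-05, and adjusted p = 0.552 with an estimated correlation), fibroblast markers 1.08 (adjusted p = 0.00035, and adjusted p = 0.552 with an estimated correlation), immune markers 0.49 (adjusted p = 0.0092, and adjusted p = 0.573 with an estimated correlation) and milk and alveolar genes -0.74 (adjusted p = 0.000184, and adjusted p = 0.503 with an estimated correlation). Their counts adjusted over the list alone were 7 of 12, 6 of 15, 1 of 18 and 6 of 16. The p63-linked epithelial list had a mean of 0.46 (adjusted p = 0.0754) and passed with outlier backgrounds replaced, with a mean of 0.72 (adjusted p = 0.012, and adjusted p = 0.343 with an estimated correlation). The remaining lists did not pass: Schwann and nerve 0.67 (adjusted p = 0.0827), muscle 0.56 (0.512), adipocyte 0.12 (0.637), cell cycle 0.06 (0.923), endothelial 0.01 (0.959), interferon response -0.01 (0.818), erythroid -0.06 (0.823) and immediate-early and heat shock genes -0.06 (0.338). Of these, the means that turned or moved by over 1.5 times with outlier backgrounds replaced were cell cycle at -0.03, immediate-early and heat shock 0.04, interferon response -0.19, endothelial 0.34, adipocyte 0.31 and erythroid -0.0035, with adjusted p between 0.151 and 0.953. The median of the interferon and erythroid lists had the opposite sign to the mean, at 0.16 and 0.06, and at 0.02 and 0.15 with outlier backgrounds replaced. By fry, lists that camera did not call with backgrounds as given passed as well. They were Schwann and nerve (adjusted p = 0.0202), muscle (adjusted p = 0.0285) and p63-linked epithelial genes (adjusted p = 0.0285).

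**Figure D1:**
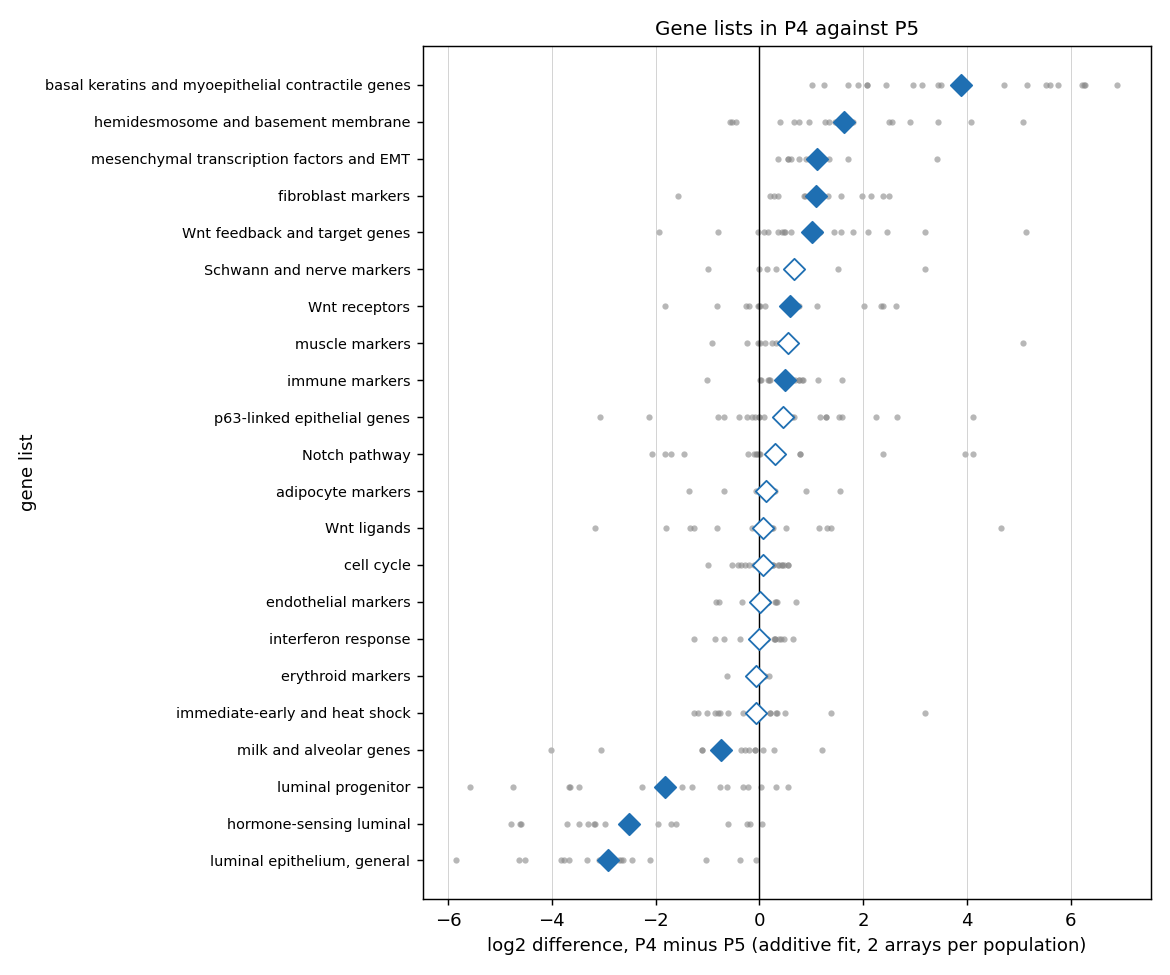
Log2 difference between P4 and P5 in the additive fit (horizontal axis) for the members of each of 22 gene lists (vertical axis). Grey points are genes and diamonds are list means, filled where camera with the preset correlation passed. The basal list has its mean at 3.89 and the general luminal list at -2.92.

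The sorted populations were next set against total MEC, which lay on the other slide, so that population and slide cannot be told apart. P4 differed from MEC in 1699 genes, 682 higher and 1017 lower, and with outlier backgrounds replaced in 4437 genes, 2364 higher and 2073 lower, with 1679 shared. P5 differed from MEC in 974 genes, 227 higher and 747 lower, and with outlier backgrounds replaced in 1515 genes, 500 higher and 1015 lower, with 922 shared. Both counts became 0 when any 1 of the WT P4, WT P5, het P4 or het P5 arrays was left out. Without WT MEC they were 4142 and 1545, and without het MEC 1243 and 2038. Trp63 was higher in P4 than in MEC by 2.13 (adjusted p = 0.03) and stood at -2.04 in P5 against MEC (adjusted p = 0.0357). Fzd7 was higher in P4 than in MEC by 1.98 (adjusted p = 0.03) and stood at -0.37 in P5 against MEC (adjusted p = 0.453). The adjusted p for both genes in P4 against MEC was 0.076 or above when any 1 of the 4 sorted arrays was left out, and for Trp63 in P5 against MEC 0.101 or above. The mean over probes lost these calls too, with Trp63 at 0.80 in P4 (adjusted p = 0.0527) and -0.66 in P5 (adjusted p = 0.0832) and Fzd7 at 1.11 in P4 (adjusted p = 0.05, just above the threshold). Median centring called Fzd7 lower in P5 than in MEC, at -1.17 (adjusted p = 0.0246).

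Stromal markers were lower in the sorted populations. Fibroblast markers had a mean of -2.25 in P4 against MEC (adjusted p = 1.75e-09, and adjusted p = 0.378 with an estimated correlation) and -3.33 in P5 against MEC (adjusted p = 8.03e-15, and adjusted p = 0.413 with an estimated correlation). In P4 8 of 15 members were called lower, 14 adjusted over the list alone, and in P5 11, 14 adjusted over the list alone. Endothelial markers stood at -1.87 and -1.88 (adjusted p = 3.56e-13 and 4.3e-14), adipocyte markers at -1.05 and -1.17 (3.04e-05 and 7.9e-07) and immune markers at -0.54 and -1.03 (0.00663 and 7.9e-07). The basal list stood at 1.88 in P4 (adjusted p = 6.43e-14) and -2.01 in P5 (adjusted p = 8.03e-15), and the general luminal list at -1.67 in P4 (adjusted p = 1.25e-08) and 1.25 in P5 (adjusted p = 9.76e-08). None of these calls held with an estimated correlation, where the lowest adjusted p was 0.335 in P4 and 0.413 in P5. The lowest gene in P5 against MEC was Dcn, a fibroblast marker, at -6.02 (SE 0.27, adjusted p = 0.015), and in P4 against MEC it was Mmp3 at -4.75 (SE 0.49, adjusted p = 0.0262). The highest were Rad51d in P4 at 4.62 (SE 0.75, adjusted p = 0.0438) and Kif12 in P5 at 3.88 (SE 0.59, adjusted p = 0.0484).

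The genotype comparison asked what heterozygous loss of ΔNp63 does in these populations. For the mean difference over the 3 populations, the smallest adjusted p in limma was 0.206. Thus limma called 0 of 24827 genes, with 5192 at an unadjusted p under 0.05. After outlier backgrounds were replaced it again called 0, with 3662 at an unadjusted p under 0.05. The P4 and P5 arrays alone, on 1 slide, gave 854 genes, 829 higher and 25 lower in het, the same count as without WT MEC or without het MEC. An offset of 0 in the background correction gave 416 genes, 262 higher and 154 lower, and median centring 7855, 701 higher and 7154 lower. Either change made together with the replacement of outlier backgrounds gave 0. On simulated shifts, made equal in all 3 populations, the same fit recovered 63.5% of probes shifted by 1. This says nothing on genotype differences that vary between populations. Across genes, the het minus WT differences correlated between P4 and P5 with r = 0.659, between P4 and MEC with 0.398 and between P5 and MEC with 0.0427. With outlier backgrounds replaced the correlations were 0.581, 0.26 and -0.0727. Position on the slide followed genotype, so these correlations cannot separate genotype from position.

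Trp63 and Fzd7 were not called by genotype with backgrounds as given or replaced. For Trp63 the mean het minus WT difference over populations was 0.40 (SE 0.21, adjusted p = 0.353). With outlier backgrounds replaced it was -0.40 (adjusted p = 0.549). For Fzd7 it was -0.33 (SE 0.20, adjusted p = 0.396), and -0.64 with outlier backgrounds replaced (adjusted p = 0.319). Median centring, which moved most genes lower in het, called Fzd7 at -1.06 (adjusted p = 0.0288), and together with replaced backgrounds it did not (adjusted p = 0.0677). Within populations the Trp63 difference was 0.89 in P4, 0.43 in P5 and -0.13 in MEC. Replacing outlier backgrounds made these -0.50, 0.35 and -1.04, and in the scanner software's log ratios -0.67, 0.35 and -0.99. With backgrounds as given, the P4 difference was also negative with median centring, at -0.45, and in the Cy5 channel alone, at -0.27. So the direction for Trp63 in P4 depends on the handling of local background, on the normalization and on the channel used. The Fzd7 difference was -0.17 in P4, 0.03 in P5 and -0.85 in MEC, and with outlier backgrounds replaced -0.80, 0.0026 and -1.14. Over the 9 settings that gave distinct values, Fzd7 ranged from -1.31 to -0.59 in MEC and from -1.45 to -0.11 in P4. The other Fzd7 probe, dimmer but above background on all 6 arrays, gave -0.33 in MEC and -0.29 in P4, and -0.06 and -0.17 with outlier backgrounds replaced. The 2 other Trp63 probes, dimmer than the one used, gave 0.16 and 0.20 in P4, and -0.59 and 0.13 with outlier backgrounds replaced. In MEC they gave 0.12 and 0.05, and 0.06 and 0.05 with outlier backgrounds replaced. The first of them was above background on 3 of the 6 arrays and the second on all 6. So the Trp63 difference of -1.04 in MEC rests on 1 probe.

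**Figure D2:**
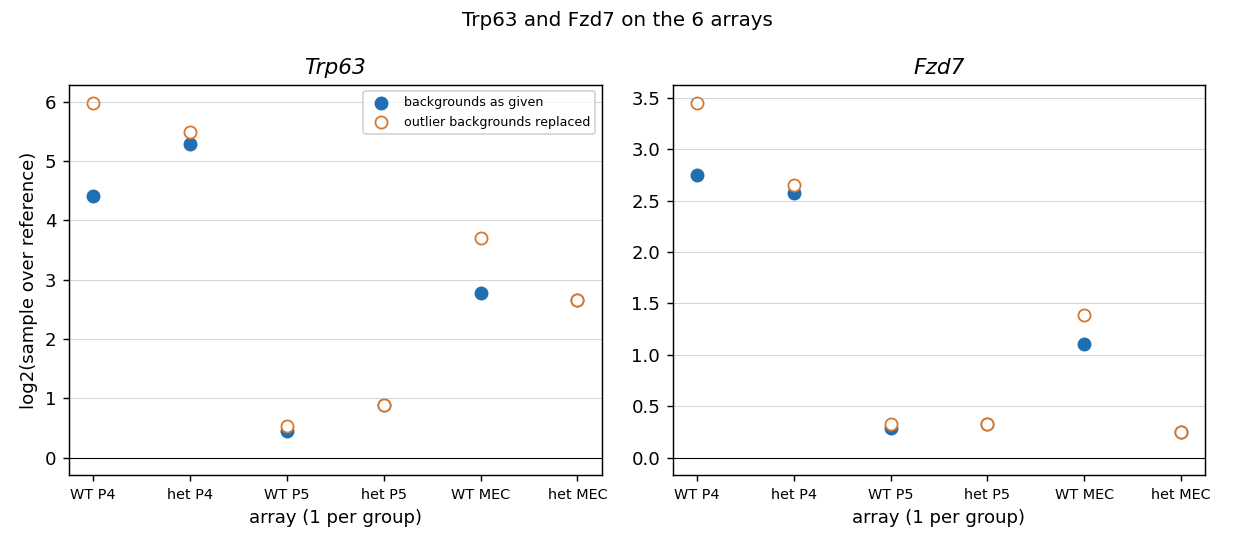
Log2 ratio of sample over reference (vertical axis) for Trp63 and Fzd7 on each of the 6 arrays (horizontal axis), 1 point per array and background treatment, without error bars because no group has a replicate. The WT P4 value of Trp63 is 4.41 with backgrounds as given and 5.99 with outlier backgrounds replaced, while het P4 stands at 5.29 and 5.48.

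Of the gene lists, 2 passed camera by genotype across populations. Without WT P5 or without het P5 7 passed, and without WT MEC or without het MEC 1. Endothelial markers had a mean of 0.68 (adjusted p = 1.6e-06), with 0 of 14 members called over all genes and 10 adjusted over the list alone, and all 14 positive. Adipocyte markers had a mean of 0.38 (adjusted p = 0.0242), with 0 of 12 members called and 3 adjusted over the list alone. Each had adjusted p = 0.986 with an estimated correlation, and by fry they had adjusted p = 0.0932 and 0.125. Neither call held with outlier backgrounds replaced, where the means were 0.24 (adjusted p = 0.226) and 0.13 (adjusted p = 0.918). The Wnt receptor list had a mean of 0.12 (adjusted p = 0.963). With outlier backgrounds replaced its mean was -0.21 (adjusted p = 0.00184, and adjusted p = 0.954 with an estimated correlation), and with the scanner software's log ratios -0.26 (adjusted p = 0.0115). Hemidesmosome genes had a mean of 0.11 (adjusted p = 0.963), and -0.17 with outlier backgrounds replaced (adjusted p = 0.0412, and adjusted p = 0.954 with an estimated correlation). The p63-linked epithelial list had a mean of 0.22 (adjusted p = 0.755), and -0.05 with outlier backgrounds replaced (adjusted p = 0.226). The remaining 17 lists had adjusted p between 0.105 and 0.963.

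In P4, 1486 of 23600 genes were at least 2-fold apart between het and WT, 1466 higher and 20 lower in het. Replacing outlier backgrounds left 999, 884 higher and 115 lower. The technical error of a difference, from probes printed 10 times, was 0.09, but no spread between animals is available and none of these differences was tested. The highest were Proz at 3.95, Cldn15 at 3.85, Fam219aos at 3.77, Gpm6a at 3.42 and P2rx2 at 3.38. The lowest were Aoc1 at -2.10, Cxcl5 at -1.59, Ifi202b at -1.42, Cpa6 at -1.30 and Cpeb2 at -1.25, and with outlier backgrounds replaced Aoc1 stood at -4.38 and Cpeb2 at -2.82. Of the lists, 7 lay outside the range of random lists. Endothelial markers had a median of 0.73, luminal progenitor genes 0.52, general luminal genes 0.39 and Wnt ligands 0.32, all above the range, and with outlier backgrounds replaced their medians were 0.13, 0.28, -0.03 and -0.0023, all within it. The Wnt feedback and target list had a median of -0.05 below a range of -0.04 to 0.31, and -0.20 with outlier backgrounds replaced, again below the range. Mesenchymal transcription factors had a median of -0.10, below the range, and 0.17 with outlier backgrounds replaced, within it. Immediate-early and heat shock genes had a median of 2.97e-05, just below the range, and -0.18 with outlier backgrounds replaced. Replacing outlier backgrounds put 5 further lists outside the range. Their medians with backgrounds as given and replaced were 0.33 and -0.11 for basal genes, 0.21 and -0.20 for hemidesmosome genes, 0.10 and -0.15 for hormone-sensing luminal genes, 0.29 and -0.09 for Wnt receptors, and 0.21 and 0.35 for fibroblast markers.

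In P5, 764 of 24145 genes were at least 2-fold apart, 630 higher and 134 lower in het, and with outlier backgrounds replaced 790, 567 higher and 223 lower. The technical error of a difference was 0.10. Calca, the gene for calcitonin, was the highest at 4.70, followed by Rspo1 at 3.11, Cldn15 at 2.99, Hmga2 at 2.97 and Proz at 2.96. The lowest were Ifi202b at -4.51, Aoc1 at -4.05, Tmem86a at -3.35, Col6a3 at -2.61 and Rasd1 at -2.19. Of the lists, 8 lay outside the range of random lists. Cell cycle genes had a median of 0.56 and 22 of 22 members were higher in het, with Cdc20 at 1.17 and Birc5 at 1.05. Basal genes had a median of 0.63 with 16 of 20 members higher, fibroblast markers 0.65 with 14 of 15, endothelial markers 0.70 with 14 of 14, mesenchymal transcription factors 0.45 with 12 of 12, immune markers 0.34 with 16 of 18 and milk and alveolar genes 0.48 with 15 of 16. General luminal genes had a median of -0.14 with 9 of 17 members lower. With outlier backgrounds replaced 7 of these 8 medians were again outside on the same side, at 0.65, 0.67, 0.69, 0.44, 0.51, 0.43 and -0.30, and milk and alveolar genes, at 0.25, were within the range. In the scanner software's log ratios the general luminal median was -0.0095, within the range. Replacing outlier backgrounds put 3 further lists outside, hormone-sensing luminal genes from -0.07 to -0.25, p63-linked genes from 0.04 to -0.08 and interferon response genes from 0.25 to 0.37. Median centring moved the median difference of all genes in P5 to -0.20 and turned the cell cycle, basal and fibroblast medians to -0.23, -0.02 and -0.10.

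In MEC, 668 of 24637 genes were at least 2-fold apart, 498 higher and 170 lower in het, and with outlier backgrounds replaced 549, 292 higher and 257 lower. The technical error of a difference was 0.08. The highest were Ptprz1 at 4.48, Muc16 at 4.02, Fxyd2 at 3.63, Aoc1 at 3.49, or 2.31 with outlier backgrounds replaced, and Grn at 3.49. The lowest were Sftpd at -4.62, Calca at -4.20, Wfdc3 at -2.76, Plac8 at -2.43 and Gbp2b at -2.39. General luminal genes had a median of 0.96 with 16 of 17 members higher in het, and hormone-sensing luminal genes 0.81 with 14 of 17. With outlier backgrounds replaced these medians were 0.32 and 0.46, both above the range, but in the scanner software's log ratios the hormone-sensing median of 0.24 lay within it. Fibroblast markers had a median of -0.44 with 12 of 15 members lower, and -0.83 with outlier backgrounds replaced. Mesenchymal transcription factors stood at -0.43, cell cycle genes at -0.45, interferon response genes at -0.40, immune markers at -0.21 and Wnt feedback and target genes at -0.12, and with outlier backgrounds replaced at -0.35, -0.23, -0.47, -0.32 and -0.27, all below the range both ways. Of the Wnt targets, Axin2 stood at -1.08 and Tcf7 at -1.60. Endothelial markers had a median of 0.55, adipocyte markers 0.36 and immediate-early genes 0.38, above the range, and with outlier backgrounds replaced 0.05, -0.03 and 0.25, within it. Replacing outlier backgrounds also put 5 further lists below the range, Wnt receptors from -0.08 to -0.40, hemidesmosome genes from 0.10 to -0.31, milk and alveolar genes from -0.01 to -0.30, basal genes from 0.05 to -0.23 and the Notch pathway from 0.07 to -0.20.

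**Figure D3:**
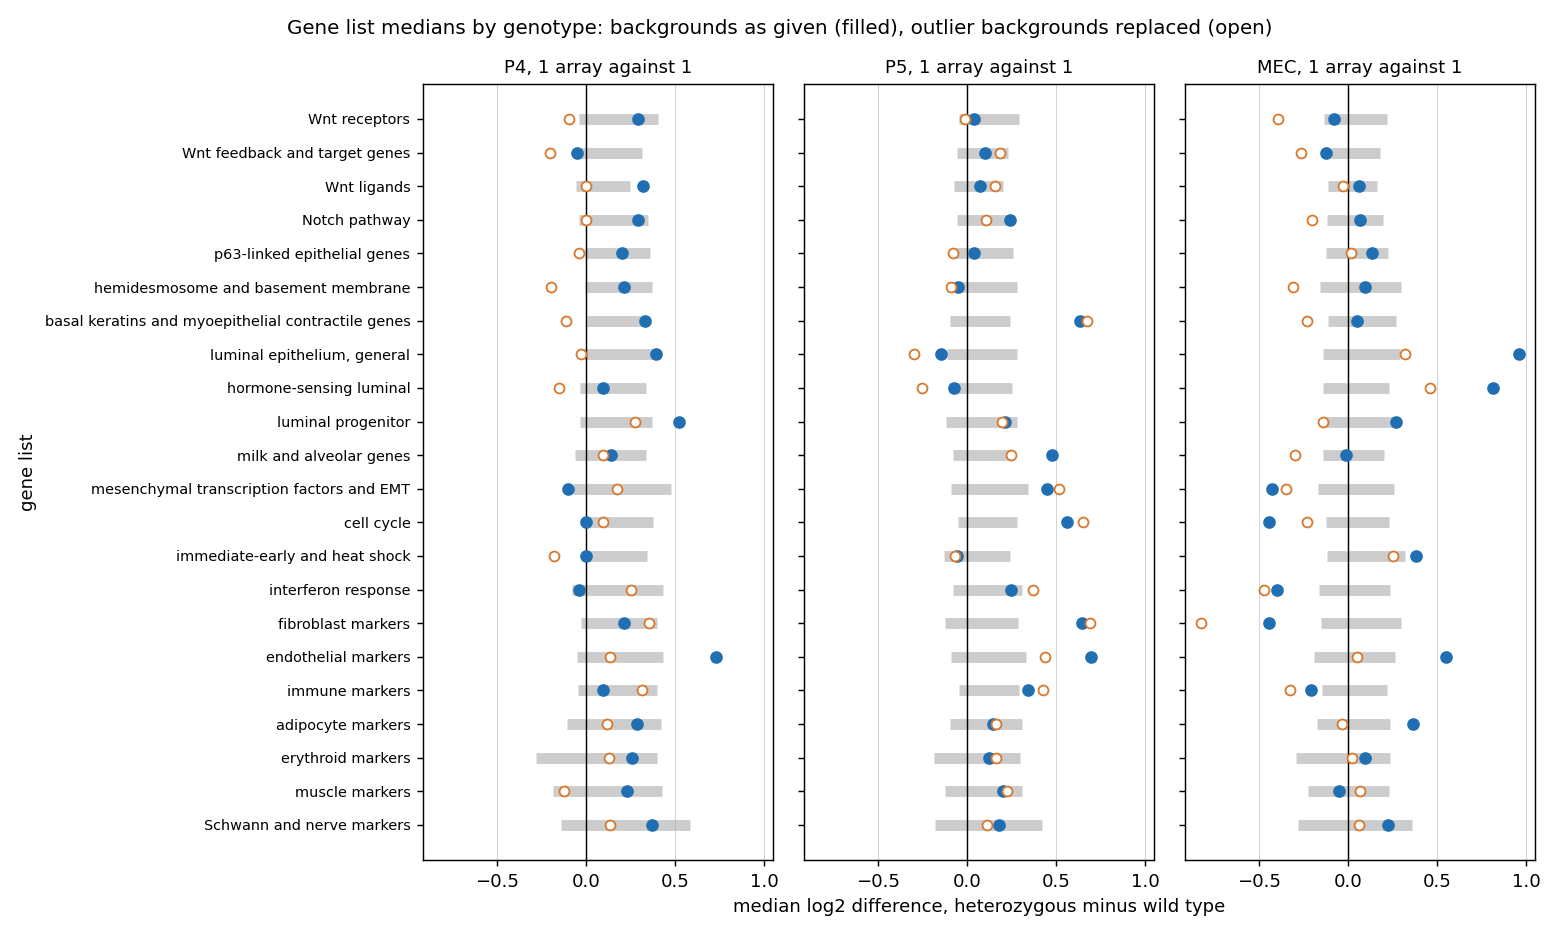
Median log2 difference of het minus WT (horizontal axis) for each gene list (vertical axis) in P4, P5 and MEC, with 1 array per group. Filled points use the backgrounds as given, open points have outlier backgrounds replaced, and grey bars span the central 95% of matched random lists for the filled points. The fibroblast list stands at 0.65 in P5 and -0.44 in MEC.

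Across the 3 populations 9 genes were at least 2-fold higher in het in all 3 and 0 were lower in all 3. The counts were 3 and 2 with outlier backgrounds replaced. The 5 named by the rule were Ugt2b34 (3.34 in P4, 2.84 in P5 and 1.15 in MEC), P2rx2 (3.38, 2.18 and 1.04), Cyth4 (2.83, 1.64 and 1.54), Gata4 (2.78, 1.68 and 1.04) and Calml3 (1.55, 1.53 and 1.62). With outlier backgrounds replaced Calml3 stood at 0.03 in P4 and 0.75 in MEC, and in MEC Ugt2b34 at 0.95 and Gata4 at 0.76.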

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

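The differences between populations in this part were not tested, as each rests on 1 array per group, and the tests of explanations and the comparison with random genes of the same log ratio were chosen after the results were seen. Each result stands here because the het minus WT difference had opposite signs in P5 and MEC, with backgrounds as given and with outlier backgrounds replaced. For a list, both medians also had to lie outside the range of random lists matched on level. A single gene had to be at least 2-fold apart in both populations.

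Among gene lists, cell cycle genes had a median het minus WT difference of 0.56 in P5 and -0.45 in MEC. Fibroblast markers stood at 0.65 and -0.44, mesenchymal transcription factors at 0.45 and -0.43, immune markers at 0.34 and -0.21 and general luminal genes at -0.14 and 0.96. Replacing outlier backgrounds made the fibroblast, cell cycle, immune and luminal medians in MEC -0.83, -0.23, -0.32 and 0.32, and the luminal median in P5 -0.30. All 10 medians lay outside the range of random lists matched on level, but this was a condition for standing here and adds no support. In the scanner software's log ratios, however, the luminal median in P5 was -0.0095, at percentile 28.4 of the random lists and so within their range. Against random genes of the same log ratio the cell cycle list in MEC, the immune list in P5 and MEC and the luminal list in P5 lay within the range with backgrounds as given, as did the mesenchymal list in P5. With outlier backgrounds replaced these were again within it, except the immune list in MEC, and the luminal list in MEC was within it too.

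Among single genes, Calca was higher in het P5 by 4.70 and stood at -4.20 in MEC. Rspo1 stood at 3.11 in P5 and -1.73 in MEC, and with outlier backgrounds replaced at -2.87 in MEC. Aoc1 stood at -4.05 in P5 and 3.49 in MEC (2.31 with outlier backgrounds replaced), Tmem86a at -3.35 and 2.35, and Muc16 at -1.17 and 4.02.

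In P5 the basal and fibroblast lists were both higher in het. One explanation is that the het P5 array reads genes far below the reference higher whatever their source. The 35 basal and fibroblast genes had a median of 0.636, above a range of 0.0414 to 0.305 for random genes of the same log ratio in P5. With outlier backgrounds replaced it was 0.693 against 0.102 to 0.392. So random genes of the same log ratio did not move as far. But both lists were taken up because they were high on these same arrays, and the range draws genes independently. The comparison therefore cannot exclude this explanation. Carry-over of P4 cells into the het P5 gate may explain the pattern: of 126 genes at least 8-fold higher in P4 than in P5, 95.2% were higher in het P5, against 69.6% of random genes of the same log ratio and 61% of all genes. Carry-over of stromal cells may explain it as well, with 95.9% of 98 genes at least 8-fold higher in MEC than in P5, against 72.6% of random genes. That set need not be stromal alone, since 10 of 20 basal list members were called lower in P5 than in MEC. Of the fibroblast markers 14 of 15 were higher in het P5, but Col6a3 stood at -2.61. Both gene sets were called in the fit of these same arrays, which favours genes whose genotype difference is alike in the populations. The random genes had no such filter, so these shares cannot show carry-over. Both kinds of carry-over stay open together with an effect of genotype on P5, which 1 array per genotype cannot separate from them. The gates on CD24 and CD29 are set to keep cells of other populations out of P5.

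In MEC the general luminal list was higher and the fibroblast list lower in het. A lower share of all stromal cells in het MEC would lower their markers alike. The endothelial median lay 0.99 above the fibroblast median, where the central range of permuted list members ended at 0.641. With outlier backgrounds replaced it was 0.877 against 0.43. But the fibroblast list was taken up for its low value on these arrays, and the permutation treats genes as independent. The endothelial median itself lay within the range for random genes of the same log ratio, at 0.55 (range 0.08 to 0.83). With outlier backgrounds replaced it was 0.05, again within the range. So the gap cannot exclude a lower share of all stromal cells. A change in fibroblasts stays open as well, but fibroblast markers were not alone. The immune median was lower too, at -0.21, and -0.32 with outlier backgrounds replaced, below random lists matched on level both ways. Against random genes of the same log ratio it left the range only with outlier backgrounds replaced. A lower share of fibroblasts and immune cells together was not tested. Another explanation is that the het MEC array reads genes below the reference as lower. The fibroblast median of -0.442 lay below a range of -0.159 to 0.438 for random genes of the same log ratio. With outlier backgrounds replaced it was -0.825 against -0.283 to 0.232. Here too the choice of the fibroblast list for its low value limits the comparison, and the range draws genes independently. So the comparison cannot exclude that reading.

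For the luminal list the same kind of reading also stays open. Its median of 0.959 lay above the range of 0.131 to 0.864 for random genes of the same log ratio, but with outlier backgrounds replaced the median of 0.318 lay within it. More luminal cells in het MEC may also contribute. The 227 genes called higher in P5 than in MEC had a median of 0.158, but -0.0191 with outlier backgrounds replaced. The first value lay above the central range of random sets, which ended at 0.0816. These genes were called on the same arrays, and the random sets had no such filter. An effect of genotype in MEC was not tested apart from these.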

How the results depend on the processing

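The replacement of outlier local backgrounds, alone or with another choice, was chosen after seeing the data, as was the test of it below; the other alternatives were planned. Among tested named genes, 1645 of 1736 alternative values for genotype and 1438 of 1836 for P4 against P5 left the call as it was, where a turn of direction between uncalled values counts as no change. For P4 against MEC it was 1208 of 1663 and for P5 against MEC 1233 of 1628. Among list tests, 412 of 462 values for genotype and 410 of 462 for P4 against P5 did. Within populations fewer values for genotype held. Named genes stayed within the technical error in 349 of 1116 values in P4, 538 of 1107 in P5 and 428 of 1101 in MEC. List medians moved by less than 0.25 of the width of the random range in 106 of 242 values in P4, 137 in P5 and 104 in MEC. The filters on dim probes leave a log2 difference as it is and the series table nearly repeats the scanner software's log ratio, so these counts overstate the number of separate checks. Except where a value or the construction of an alternative shows it, the cause was not tested.

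An offset of 0 gave 416 genotype genes, 1604 genes for P5 against MEC and 4 genotype lists. It gave 2617, 1580 and 1860 genes at least 2-fold apart in P4, P5 and MEC, and 5 lists outside the random range in P5.

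The scanner software's log ratio gave 4362 genes for P4 against MEC, 1599 for P5 against MEC, 1 genotype list, and 1715 and 1347 genes apart in P5 and MEC. The series table gave 4349, 1597, 1, 1715 and 1346. Wnt receptors by genotype turned to -0.26 (adjusted p = 0.0115 and 0.0118), and immediate-early genes in P4 to -0.27 in both. The Cy5 channel alone gave 3693 and 1612 genes for P4 and P5 against MEC, 0 genotype lists, 901 genes apart in P4, and immediate-early genes in P4 at -0.18.

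Median centring leaves a trend with intensity in the log ratios and moved the median genotype difference of all genes to -0.37 in P4, -0.20 in P5 and -0.04 in MEC. It gave 7855 genotype genes, 904 genes for P4 against P5, 7023 for P4 against MEC, 8275 for P5 against MEC and 4 genotype lists. It gave 8927, 2304 and 1905 genes apart in P4, P5 and MEC, and 11 lists outside in P4. By genotype, Cd151 turned to -0.72, Sox10 to -0.64, the cell cycle list to -0.92 and the immediate-early list to -0.96. Hsph1 in P4 against MEC turned to -0.22. Within P4 the general luminal list turned to -0.29 and luminal progenitor genes to -0.037, within P5 the basal list to -0.019, cell cycle to -0.23 and fibroblast markers to -0.10, and within MEC immediate-early genes to -0.47.

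The strict filter left 1 genotype list and the mean over probes gave 4. P4 and P5 arrays alone gave 854 genotype genes, 4639 genes for P4 against P5 and 1 genotype list. A trended robust prior gave 3989 genes for P4 against P5. With an estimated correlation 0 lists passed by genotype and 0 in P4 against P5, also with outlier backgrounds replaced, and fry gave 0 by genotype. A log2 size of 1.5 left 614, 235 and 218 genes apart in P4, P5 and MEC, as a stricter limit must give fewer.

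Outlier backgrounds replaced gave 4437 genes for P4 and 1515 for P5 against MEC. By genotype Wnt receptors turned to -0.21 (adjusted p = 0.00184) and hemidesmosome genes to -0.17 (adjusted p = 0.0412), and immediate-early genes in P4 to -0.18. With an offset of 0 as well there were 4611 and 1949 genes against MEC, 1 genotype list and 1414 genes apart in P5, with Wnt receptors at -0.24 and immediate-early genes in P4 at -0.19. With median centring as well there were 4828 genes for P4 against P5, 16490 for P4 and 14426 for P5 against MEC, and 811 genes apart in P4. Against MEC in P4, Mki67 turned to -0.87, Cdc20 to -0.92, Hsph1 to -0.59, Hba-a1 to -0.59 and Pmp22 to -1.41, and in P5 Hba-a1 to -0.56. By genotype Wnt receptors turned to -0.35, hemidesmosome genes to -0.51 and immediate-early genes to -0.50. Cell cycle genes in P4 against P5 turned to -0.43, and immediate-early genes to -0.85 within P4 and -0.15 within MEC.

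Leaving out 1 array leaves 1 residual degree of freedom, and the lone array of a group is assumed to vary like the others. Genotype genes ranged from 0 to 854, the latter without WT MEC or het MEC. P4 against P5 ranged from 0 to 4639, P4 against MEC from 0 to 4142 and P5 against MEC from 0 to 2038, with 0 without any of WT P4, WT P5, het P4 or het P5. Genotype lists ranged from 1 to 7, the latter without WT P5 or het P5, and P4 against P5 lists from 11 to 14. The genotype mean of mesenchymal transcription factors ranged from -0.10 to 0.38 and that of cell cycle genes from -0.24 to 0.28, the lowest without WT P5 or het P5. Cell cycle genes in P4 against P5 ranged from -0.36 without WT P5 to 0.49 without het P5.

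A candidate explanation for the genotype differences that moved with the background is the normexp fit itself, drawn off by a few bright local backgrounds. All backgrounds marked as outliers by the scanner software were replaced, the bright ones among them. The correlation across genes with the software's log ratios then rose by 0.22 in P4, from 0.617 to 0.837. In P5 it stood at 0.852 before and 0.855 after, and in MEC it rose from 0.723 to 0.873. These correlations alone do not single out the few bright backgrounds, but the fitted background means do. Het P5 had 0 backgrounds above 100. Replacing 753 in Cy5 and 237 in Cy3 there moved the Cy5 mean from -4.62 to -4.44 and left Cy3 at -2.88. WT P4 had 14 and 13 above 100, and its means went from -116.77 to -2.11 and from -558.69 to -0.83. On WT P5 the Cy3 mean went from -93.15 to -2.22, although the P5 correlation hardly changed. The marks and the log ratios also come from the same software, so part of the rise may be built in. Trp63 was lower in het P4 in 7 of 12 settings, or in 6 of 9 with equal values counted once. These settings are not separate votes. It was higher only in settings that took log ratios after loess with backgrounds as given. WT P4 stood at 4.41 with backgrounds as given and 5.99 with outlier backgrounds replaced, while het P4 moved from 5.29 to 5.48. So in the loess log ratios the direction turned mainly with the WT P4 array. Whether Trp63 is lower in het P4 stays open, since no spread between animals exists. Another probe stood at 0.13 with outlier backgrounds replaced.

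Beyond the population term of the fit, which matches WT with het, no paired analysis was possible because each group holds 1 array. Quantile normalization between arrays left the log ratios as they were and slide as a block changed nothing in the tests of genotype and P4 against P5, so neither gave a value of its own. Signal over background limits dim genes: the median Cy5 signal was 3.28 to 5.22 times the background, and the fold of a gene dim on 1 side is uncertain.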

Other observations

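The split tests in this part were planned, and the comparison with random genes of the same log ratio was chosen after the lists had been seen.

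With 6 arrays divided 3 against 3 there are 10 splits, too few for a share under 0.05. The real division by genotype gave 0 genes and the highest other split 0, and that 10 of 10 splits gave as many was fixed by the 0 and says nothing on chance. The real division gave 2 gene lists and the highest other split 11, and 8 of 10 splits gave as many. With population in the fit the 10 splits are only 7 distinct fits, and 6 of the 10 splits compare WT with het in 1 population alone, the 2 with 11 lists doing so in MEC. The splits therefore hold genotype differences themselves, and this share says nothing on chance either.

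Against random genes of the same log ratio, the Wnt feedback and target list lay below the range in het P4 at -0.05 (range 0.01 to 0.40) and in het MEC at -0.12 (range -0.08 to 0.27). With outlier backgrounds replaced it lay below the range again in both, at -0.20 and -0.27, while in P5 it was within the range at 0.10. Wnt receptors in het MEC lay below the range at -0.08, and at -0.40 with outlier backgrounds replaced. This is not particular to Wnt genes: the milk and alveolar, mesenchymal, interferon response and fibroblast lists in het MEC and the immediate-early list in het P4 also lay below the range both ways. These are values of 1 array against 1, and the difference between populations was not tested.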
